A study of Homo sapiens with 30 samples.

How the data were processed

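RNA of sorted cells of subclones 2 and 13 of MDA-MB-231 was measured in primary tumours, lung metastases and liver metastases of 3 mice, and in a retransplantation experiment with subclone 2 from 3 further mice, per the labels. Total RNA was isolated with a column kit that includes a DNase step and libraries were made with the Illumina TruSeq RNA Library Prep Kit v2, per the labels' protocols. That kit does not keep the strand, so reads of overlapping genes on opposite strands could not be told apart. The tools bcl2fastq 2.15.0.4, cutadapt, STAR and featureCounts and the genome GRCh38 were named, per the submitters' processing notes, without the role or order of each. The values deposited by the authors were read counts per gene, 1 column per library, in 2 tables of 38526 and 36291 genes that share 33867 genes. Both tables held whole numbers, and they were analysed separately except in the test of the difference between the experiments, which used the shared genes. Gene coordinates and types were taken from GENCODE v29, and gene symbols from a separate list of current and older gene names.

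The 30 libraries had 6.54 to 72.0 M (1 M is 1e+06) counts in the first experiment and 23.4 to 32.3 M in the second. For subclone 13 of mouse 1 each organ had 3 libraries, from sequencing runs 1, 2 and 3; these were summed, because 6 of these 9 libraries are called technical replicates, per the labels. Their biological coefficient of variation (BCV) was 0.117 in liver, 0.0901 in lung and 0.0676 in tumour. The resulting 18 samples had 11.8 to 82.2 M counts. All other libraries of a mouse came from 1 run, per the sample sheet of the authors, so in the first experiment run and mouse could not be separated outside these 9 libraries. The 6 retransplantation libraries, from 3 mice, all came from run 4, so differences between those mice were not differences between runs.

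Genes were kept with filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 17418 genes in the first experiment, 17549 in the second and 18950 in the joint fit. Counts were scaled by TMM and fitted with all groups of an experiment together. Comparisons were tested with the quasi-likelihood F test of edgeR, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Standard errors were computed as the size of the log2 fold change divided by the square root of F. The design, the comparisons, 35 gene lists and the rule for the genes to be named were written before the data were examined. In total 14 comparisons were made: 3 organ pairs in each of 2 subclones, the subclones in each of 3 organs, the differences between the subclones in the 3 organ pairs, lung against liver in the retransplantation samples and its difference from the first experiment.

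Samples with the same number came from the same mouse, per the labels. In the first experiment they mostly shared a sequencing run as well, so correlations between them cannot tell mouse from run. Deviations from the group means had a median correlation of 0.44 over 45 pairs from the same mouse (lowest 0.0535) and of -0.30 over 90 pairs from different mice. Such deviations cancel out within a group, so positive values within mice force negative ones between mice. In the retransplantation samples the median over 3 pairs from the same mouse was 0.34. The fit with mouse number as an additive replicate block had been planned as an alternative, and it lowered the BCV from 0.476 to 0.330 in the first experiment and from 0.296 to 0.227 in the second.

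Genes were named when they had a symbol, an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and all 3 samples of 1 group above all 3 of the other. For each organ pair the rule took up to 8 genes higher and 8 lower in both subclones, ranked by the smaller of the 2 changes, and up to 5 each way per subclone. It took up to 10 each way for genes called between the subclones in all 3 organs and for the retransplantation samples, and 5 each way for the differences between subclones. After the data had been seen the same rule was applied to the fit with mouse as a term. Members of the lists are named because the lists were fixed. Results for 3 single genes that met these rules are not reported here. Such CPM values are scaled by TMM, except those of host transcripts and of the mitochondrial share, which use total counts.

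Lists with at least 3 tested members (33 of 35) were tested on voom values with camera in limma 3.58.1, with the preset correlation of 0.01 and again with a correlation estimated from the data, with adjustment over the lists of a comparison. Members were also adjusted over their list alone. Genes taken from lung against liver in the first experiment were tested in the retransplantation samples with fry. The alternatives were DESeq2 1.42.0, no filter on low counts, other size factors (RLE), only the groups compared, leaving out each sample and each mouse, and 1 library in place of the 3 summed libraries. RLE scaling changed the sign of 12 of 462 list medians and of 0 of the 149 called ones. Labels were also regrouped within the compared samples, in every possible way for 3 samples against 3, and in 19 other groupings drawn at random with a fixed seed for the differences between subclones and between experiments.

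The pipeline was tested on simulated data with 200 changed genes. In lung against tumour of subclone 2, the fit without a mouse term recovered 8.82%, 69.7% and 86.4% of genes changed by 1, 2 and 3 on the log2 scale, and the fit with that term recovered 45.6%, 84.8% and 98.5%. The counts were simulated from the fit with that term, with additive mouse effects, so its better recovery was partly built in. Unchanged genes made up 0% and 1.30% of the calls, and over all 14 comparisons at most 0.980% and 6.71%. A simulated list with risen members was called, a list with mixed changes was not, and 0 of 33 random lists were called. Apart from the mouse effects the simulated genes varied independently, and the lists were drawn at random. The simulation could therefore not test list calls for genes that vary together. No genome sequence was used, reads were not analysed here, and mouse reads could be judged only from counts on human genes.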

Results

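The data were gene counts of 2 subclones (2 and 13) of the human breast cancer line MDA-MB-231, each sorted from primary tumours, lung metastases and liver metastases of the same mice. The first experiment held 6 groups of 3 mice (18 samples from 24 libraries, 11.8 to 82.2 M counts per sample). The retransplantation experiment held 6 samples of subclone 2, labelled lung or liver metastasis, from 3 other mice (23.4 to 32.3 M counts per sample). Its labels do not say whether the organ is the origin of the transplanted cells or the place where they grew. The calls below are from edgeR fits without a mouse term, which were set before the data were examined. Those fits do not use the pairing of samples from the same mouse. Counts of called genes and many list results are also given from the planned fit with mouse as a term, but most single genes are given without that term. Every gene called without the mouse term was also called with it. Each mouse of the first experiment had its own sequencing run, apart from the subclone 13 libraries of mouse 1, so that term takes up differences between mice and between runs. Every gene named for a comparison had all 3 samples of 1 group above all 3 of the other, unless it is given as a member of a list.

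The samples of mouse 1 stood apart from those of mice 2 and 3 on the first principal component, which held 32.9% of the variance. The second component, with 13.3%, separated the subclones, and on the third, with 11.4%, all 6 tumour samples (17.9 and above) lay above all 12 metastasis samples (17.7 and below). The score of 17.7 was that of the subclone 2 liver sample of mouse 2; the other 11 metastasis samples had scores of -2.40 and below. Samples of the same mouse shared their deviations from the group means: across genes, the median correlation of these deviations was 0.44 over 45 pairs from the same mouse and -0.30 over 90 pairs from different mice. Such deviations cancel out within a group, so positive values within mice force negative ones between mice. Samples of 1 mouse mostly shared a sequencing run too, so these correlations could not tell mouse from run.

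**Figure D1:**
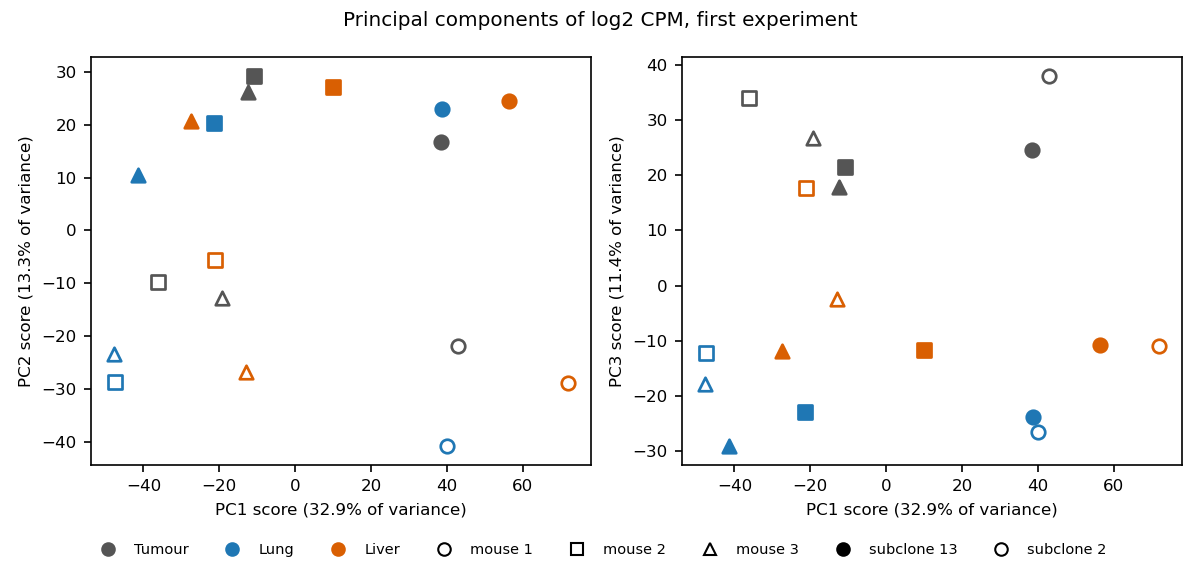
Scores of the 18 samples of the first experiment on principal components 1 to 3 of log2 CPM, with colours for organ, shapes for mouse and filled symbols for subclone 13. The 6 samples of mouse 1 lie to the right of all others on component 1 (32.9% of variance).

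Lung metastases of both subclones differed from primary tumours in single genes such as ID1, SOCS3 and SPRY1, in matrix genes and in mitochondrial transcripts. ID1, which blocks basic helix-loop-helix transcription factors, rose by 3.66 ± 0.34 (log2 fold change ± SE) in subclone 2, from 42.7 ± 1.65 to 539 ± 26.5 CPM (mean ± SD, n = 3), with an edgeR adjusted p of 4.68e-05. In subclone 13 ID1 rose by 2.98 ± 0.33, from 51.3 ± 16.1 to 404 ± 76.7 CPM, with an adjusted p of 0.000335. Its relative ID3 rose by 1.95 ± 0.33 in subclone 2 and by 1.66 ± 0.32 in subclone 13. SOCS3, a feedback inhibitor of cytokine receptors, rose by 2.92 ± 0.46 and 2.52 ± 0.46, SPRY1, an inhibitor of receptor tyrosine kinase signalling, by 1.97 ± 0.24 and 2.36 ± 0.24, and ARRDC3, an arrestin-like protein, by 1.80 ± 0.30 and 1.95 ± 0.31. B3GNT7, a glycosyltransferase, rose by 1.67 ± 0.36 and 1.66 ± 0.35. RASD1 and SLC47A1 were among the largest rises in subclone 2 (2.68 ± 0.53 and 2.64 ± 0.52), and TNFSF4, TFF3 and GYPC among those in subclone 13 (3.38 ± 0.63, 3.19 ± 0.66 and 3.15 ± 0.67). With only the groups compared edgeR lost RASD1 and SLC47A1 (adjusted p = 0.158 and 0.151). GYPC was lost with RLE scaling (0.0501). With 1 library in place of the 3 summed, TFF3 (0.0581 and 0.0556) and GYPC (0.0660 and 0.0584) were lost.

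Genes of the extracellular matrix fell in the lung. COL1A2, a chain of type I collagen, fell by 2.99 ± 0.41 in subclone 2 (from 112 ± 22.7 to 14.1 ± 2.13 CPM) and by 2.72 ± 0.41 in subclone 13 (from 159 ± 17.4 to 24.1 ± 4.20 CPM), with adjusted p of 0.00294 and 0.00566. TNC, a matrix glycoprotein, fell by 1.92 ± 0.23 and 1.94 ± 0.23, COL6A3 by 1.94 ± 0.32 and 2.4 ± 0.32, and TGFBI, a matrix protein induced by TGF-beta, by 2.53 ± 0.38 and 2.48 ± 0.38. CCDC80 fell by 1.84 ± 0.34 and 2.14 ± 0.34. LRP1, an endocytic receptor, fell by 2.26 ± 0.37 and 2.04 ± 0.37, and ITPR1, a calcium channel of the endoplasmic reticulum, by 1.98 ± 0.27 and 2.33 ± 0.28. L1CAM, a cell adhesion molecule, and NFATC2, a transcription factor, fell in subclone 2 (by 2.36 ± 0.43 and 2.10 ± 0.43). With only the groups compared edgeR lost both (adjusted p = 0.0584 and 0.115). L1CAM was also lower in the lung samples of subclone 13 (30.7 to 53.3 CPM) than in its tumour samples (96.5 to 133 CPM). THBS2, a matrix glycoprotein, and LINC03040 fell in subclone 13 (by 4.41 ± 0.94 and 2.52 ± 0.40). THBS2 was lost in edgeR with RLE scaling (adjusted p = 0.0501) and with only the libraries not labelled technical (0.0576).

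Among the lists fixed beforehand, 6 of 24 collagen and matrix genes fell in subclone 2 and 18 did not pass, and 5 fell and 19 did not pass in subclone 13. Adjusted over the list alone, 13 and 14 fell; with mouse as a term, 12 and 10 fell. The list medians were -1.20 and -1.19, and camera called the list in both subclones, also with an estimated correlation (adjusted p = 0.0376 and 0.0135 with an estimated correlation). The call held in subclone 13 alone with mouse as a term (adjusted p = 0.0742 and 0.0357 with an estimated correlation). COL4A1 fell by 1.88 ± 0.30 and 1.57 ± 0.30 and LAMC1 by 1.36 ± 0.22 and 1.32 ± 0.22. A list of 11 fibroblast, stellate and smooth muscle markers, which shares COL1A2, had 1 member fall in each subclone, with medians of -0.35 and -0.75 (camera adjusted p = 0.0881 and 0.00542; adjusted p = 0.397 and 0.173 with an estimated correlation). Of 17 matrix proteases and inhibitors, 1 fell in each subclone, MMP14, a membrane-bound metalloprotease (by 1.20 ± 0.24 and 1.25 ± 0.25); the adjusted p with an estimated correlation were 0.376 and 0.101.

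Of 13 mitochondrially encoded genes, 8 rose in each subclone and 5 did not pass, while 12 and 13 rose when adjusted over the list alone and all 13 rose in both with mouse as a term. MT-ND4, a subunit of complex I, rose by 1.64 ± 0.30 and 1.98 ± 0.30, and MT-ATP6, a subunit of the ATP synthase, by 1.46 ± 0.25 and 1.53 ± 0.25. The list medians were 1.37 and 1.5 (adjusted p = 0.0376 and 0.0135 with an estimated correlation), and with mouse as a term that call was likewise lost in subclone 2 and held in subclone 13 (adjusted p = 0.0742 and 0.0357 with an estimated correlation). These genes held 10.3 ± 0.438% of the counts in subclone 2 lung samples against 4.72 ± 0.513% in tumour samples, and 11.2 ± 0.530% against 5.09 ± 0.532% in subclone 13. The 22 nuclear genes of oxidative phosphorylation had medians of 0.33 and 0.26, with 0 members past the threshold in either subclone (camera adjusted p = 0.0167 and 0.00975; adjusted p = 0.651 and 0.556 with an estimated correlation).

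Of 19 immediate early genes, 3 rose in subclone 2 (DUSP1, ZFP36 and IER2) and 2 in subclone 13 (DUSP1 and ZFP36), and none fell. DUSP1, a phosphatase of MAP kinases, rose by 2.50 ± 0.45 and 2.21 ± 0.44, and ZFP36, which destabilizes cytokine transcripts, by 2.88 ± 0.52 and 2.56 ± 0.51. Adjusted over the list alone, 9 and 6 rose, and with mouse as a term 9 and 5 rose. The camera calls (adjusted p = 1.76e-14 and 7.51e-09) did not hold with an estimated correlation (adjusted p = 0.186 and 0.227 with an estimated correlation). Of 17 genes of the TGF-beta response, ID1 and ID3 rose and TGFBI and LTBP2 fell in each subclone, and 13 did not pass (camera adjusted p = 0.306 and 0.0964). Of 28 interferon response genes, none passed in subclone 2, where 2 fell adjusted over the list alone. In subclone 13, 3 fell (IFIT3 by 1.80 ± 0.32, HERC5 by 1.68 ± 0.32 and IFIT2 by 1.64 ± 0.34), and 8 fell adjusted over the list alone (adjusted p = 0.227 with an estimated correlation).

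In all, 76 of 17418 genes differed between lung metastasis and tumour in subclone 2 (32 higher, 44 lower) and 73 in subclone 13 (26 higher, 47 lower). Of these, 19 were higher and 25 lower in both subclones and none were opposite. The subclones came from the same mice, so the 2 sets of calls are not independent. With mouse as a term 532 and 503 genes were called, and DESeq2 called 337 and 307. The counts depended on single samples and mice: leaving them out gave 2 to 97 genes in subclone 2 and 0 to 145 in subclone 13, and a fit of the 6 compared samples alone gave 18 and 103.

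**Figure D2:**
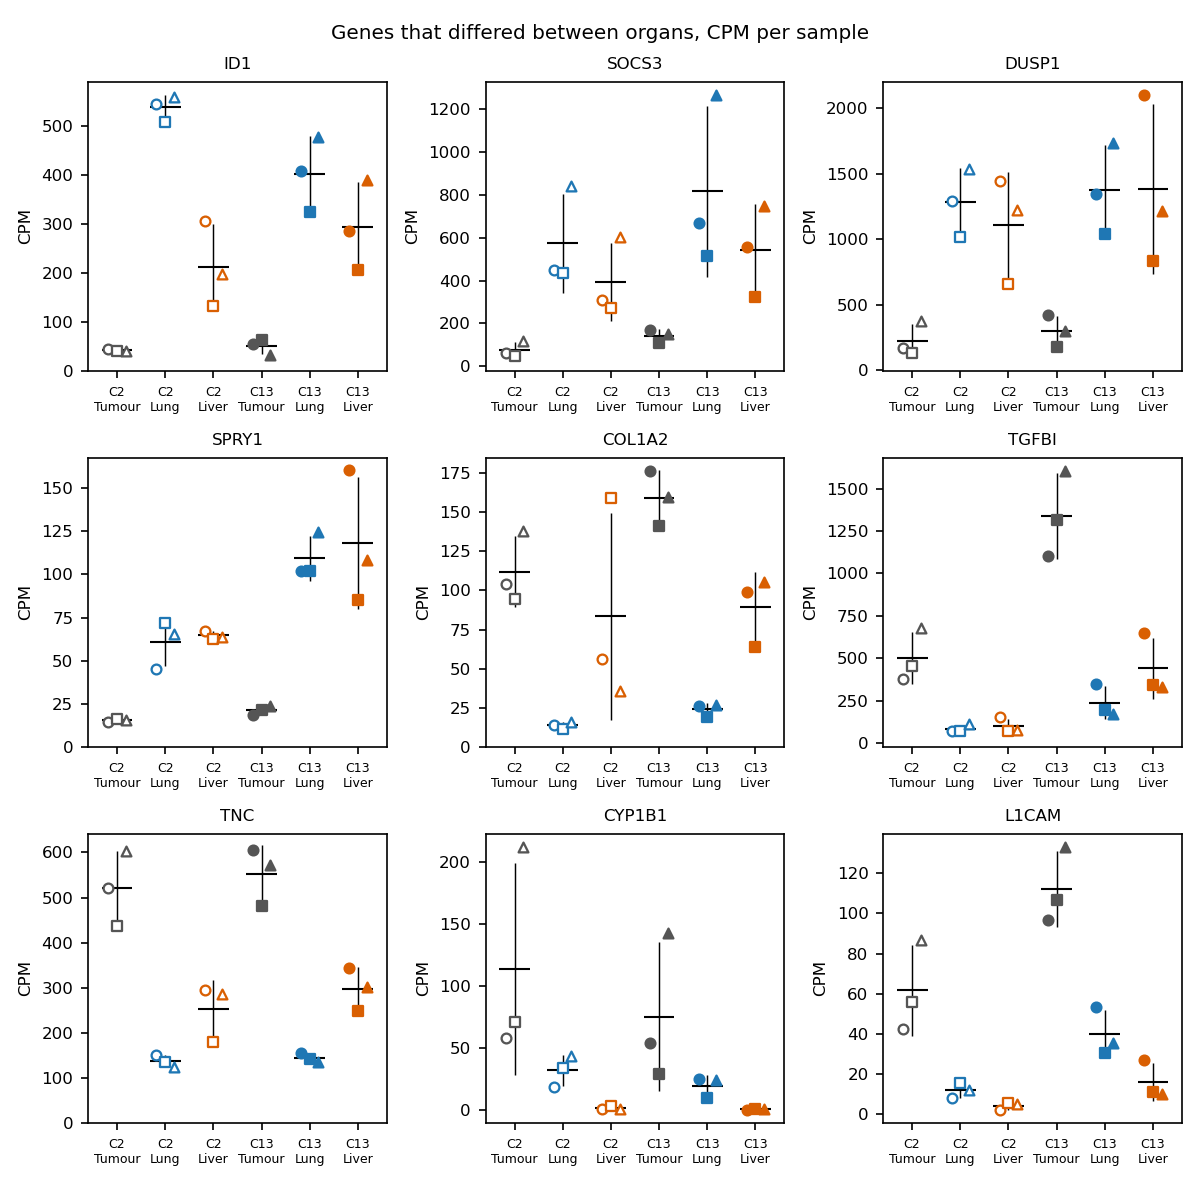
CPM (TMM-scaled) of 9 genes in each sample of the first experiment, by subclone (C2, C13) and organ; symbols are mice 1 (circle), 2 (square) and 3 (triangle), horizontal lines are means and vertical lines are SD (n = 3). ID1 averaged 42.7 CPM in subclone 2 tumours and 539 CPM in its lung metastases, and COL1A2 averaged 112 and 14.1 CPM.

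Liver metastases differed from primary tumours most strongly in lower transcripts. CYP1B1, a cytochrome P450 induced by the aryl hydrocarbon receptor, fell by 6.25 ± 0.86 in subclone 2 (from 114 ± 85.6 to 1.40 ± 1.57 CPM; edgeR adjusted p = 0.00357). In subclone 13 CYP1B1 fell by 7.59 ± 0.97 (from 75.3 ± 59.9 to 0.443 ± 0.231 CPM; adjusted p = 0.00137). L1CAM fell by 3.84 ± 0.45 and 2.78 ± 0.43, PTX3, a soluble pattern recognition protein, by 3.04 ± 0.57 and 2.69 ± 0.56, and EDN1, the precursor of endothelin 1, by 2.32 ± 0.43 and 2.85 ± 0.44. WWC1, a protein of the Hippo pathway, fell by 2.82 ± 0.42 and 3.05 ± 0.42, STX11, a syntaxin, by 2.57 ± 0.51 and 3.07 ± 0.51, and MFSD2A, a lipid transporter, by 1.94 ± 0.40 and 2.31 ± 0.41. DIO2, an enzyme that activates thyroid hormone, and IL11, a cytokine, fell in subclone 2 (by 5.44 ± 1.09 and 3.39 ± 0.63), and in subclone 13 THBS2 fell by 6.19 ± 1.04, IL12A fell by 3.85 ± 0.65 and ADAMTS12 fell by 3.20 ± 0.63.

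Fewer genes were higher in the liver. DDIT4, a stress-induced inhibitor of mTORC1, rose by 2.77 ± 0.48 in subclone 2 (from 32.0 ± 8.36 to 219 ± 134 CPM) and by 2.52 ± 0.47 in subclone 13 (from 61.0 ± 33.4 to 351 ± 167 CPM), with adjusted p of 0.0163 and 0.0177. PPP1R3B, which targets protein phosphatase 1 to glycogen, rose by 1.61 ± 0.23 and 1.73 ± 0.23. ID1 rose by 2.31 ± 0.32 and 2.52 ± 0.32, DUSP1 by 2.30 ± 0.45 and 2.22 ± 0.44, SPRY1 by 2.05 ± 0.24 and 2.47 ± 0.25 and ARRDC3 by 1.97 ± 0.31 and 1.92 ± 0.31; the same tumour samples served as reference for the lung. XIRP2, an actin-binding protein, and SOCS3 were called higher in subclone 2 (by 3.94 ± 0.73 and 2.38 ± 0.45), and TFF3, a secreted mucosal peptide, in subclone 13 (by 3.59 ± 0.67). SOCS3 was also higher in the liver samples of subclone 13 (324 to 750 CPM) than in its tumour samples (108 to 168 CPM).

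Of 26 genes of the TNF and NF-kB response, all had lower fitted values in both subclones. NFKB1 alone passed in subclone 2 (fell by 1.04 ± 0.19), and NFKB1, RELB and IRAK2 passed in subclone 13 (fell by 1.79 ± 0.19, 1.79 ± 0.30 and 1.77 ± 0.25). Adjusted over the list alone 8 and 21 fell, and with mouse as a term 5 and 8 fell. The medians were -1.06 and -1.78 (adjusted p = 0.0579 and 0.0402 with an estimated correlation), so only the call in subclone 13 held, also with mouse as a term (adjusted p = 0.0999 and 0.0466 with an estimated correlation). Of 28 interferon response genes, 0 passed in subclone 2 and 4 fell in subclone 13 (IFIT1 by 2.4 ± 0.46, IFIT2 by 2.25 ± 0.35, IFIT3 by 2.22 ± 0.33 and HERC5 by 1.66 ± 0.32). Adjusted over the list alone 18 and 11 of them fell, and with mouse as a term 14 and 11 fell. The interferon medians were -1.31 and -1.15, and both camera calls were lost with an estimated correlation (adjusted p = 0.0550 and 0.0803 with an estimated correlation), while with mouse as a term that of subclone 13 passed (adjusted p = 0.0657 and 0.0466 with an estimated correlation).

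Of 23 genes of cholesterol synthesis and uptake, 0 passed in subclone 2 and 4 fell in subclone 13, among them INSIG1 by 1.78 ± 0.36 and SQLE by 1.23 ± 0.21. Adjusted over the list alone 8 fell in each subclone, and with mouse as a term 6 and 7 fell. The medians were -0.46 and -0.55, and the camera calls held with an estimated correlation (adjusted p = 0.0266 and 0.0153 with an estimated correlation), but with mouse as a term only that of subclone 13 did (adjusted p = 0.0693 and 0.0466 with an estimated correlation). Of 24 collagen and matrix genes, 2 fell in subclone 2 (COL4A1 by 1.69 ± 0.30 and COL5A1 by 1.66 ± 0.32) and 1 in subclone 13 (COL6A3 by 1.5 ± 0.31), with medians of -0.48 and -0.83 (adjusted p = 0.0343 and 0.0402 with an estimated correlation, and 0.0856 and 0.0466 with mouse as a term). The 11 fibroblast, stellate and smooth muscle markers had 0 members past the threshold and medians of -1.06 and -0.74 (camera adjusted p = 0.000298 and 0.0437; adjusted p = 0.0550 and 0.231 with an estimated correlation). The 25 genes of mitosis had 0 members past the threshold and medians of 0.49 and 0.47 (camera adjusted p = 6.98e-06 and 1.60e-05; adjusted p = 0.404 and 0.355 with an estimated correlation). The mitochondrially encoded genes had 0 of 13 members past the threshold and held 4.49 ± 1.22% and 4.56 ± 0.625% of the counts in the liver samples. ALB, a hepatocyte transcript, averaged 0.00642 and 0.101 CPM in the liver samples of subclones 2 and 13.

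In liver metastasis 50 genes differed from the tumour in subclone 2 (15 higher, 35 lower) and 67 in subclone 13 (16 higher, 51 lower). In both subclones 6 were higher and 17 lower, and none were opposite. With mouse as a term 292 and 318 genes were called, and DESeq2 called 255 and 237. Leaving out samples or mice gave 0 to 99 genes in subclone 2 and 0 to 121 in subclone 13; fits of the 6 compared samples alone gave 0 and 30.

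**Figure D3:**
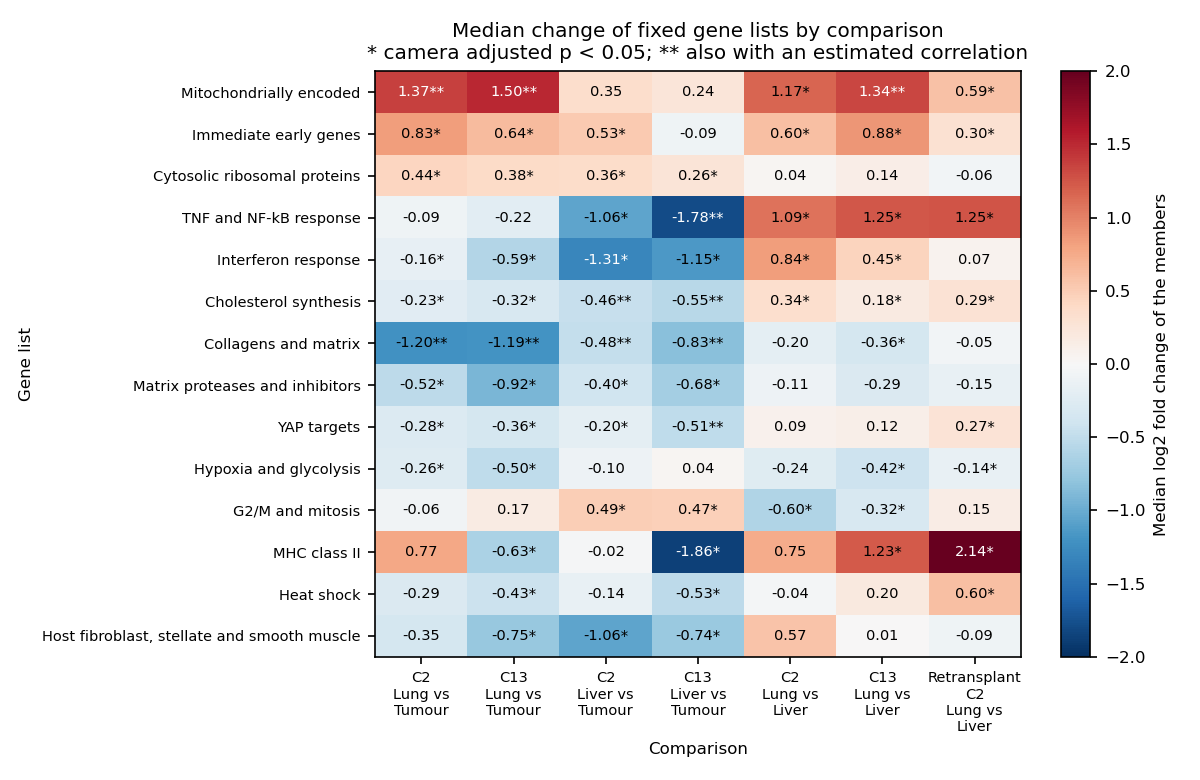
Median log2 fold change of the members of 14 gene lists in 7 comparisons, from -2 (blue) to 2 (red); 1 asterisk marks a camera adjusted p under 0.05 with the preset correlation, and 2 asterisks mark calls that also held with an estimated correlation, in fits without a mouse term. The mitochondrially encoded list had medians of 1.37 and 1.5 in lung against tumour, and the TNF and NF-kB list had medians of -1.06 and -1.78 in liver against tumour.

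Between lung and liver metastases, 4 genes differed in subclone 2. SLC43A2, an amino acid transporter, was higher in the lung by 2.70 ± 0.38 (32.6 ± 13.0 against 4.94 ± 2.33 CPM; edgeR adjusted p = 0.0207). COL1A2 was lower in the lung (-2.57 ± 0.41; 14.1 ± 2.13 against 83.6 ± 65.9 CPM; adjusted p = 0.0402), as were EDNRA, an endothelin receptor (-1.97 ± 0.32), and CLMP, an adhesion molecule (-1.60 ± 0.26). The liver sample of mouse 2 held 159 CPM of COL1A2 and the other 2 held 56.0 and 36.0 CPM. Without that sample the change was -1.7 (adjusted p = 0.0407). DESeq2 called 277 genes in subclone 2. A fit of the 6 compared samples alone called 0 (adjusted p = 0.669 for SLC43A2 and 0.682 for COL1A2). EdgeR called 0 without the lung sample of mouse 2 or that of mouse 3 and 135 without mouse 1. In subclone 13 edgeR called 0 genes, with a smallest adjusted p of 0.119; 792 genes had an unadjusted p under 0.05, and DESeq2 called 51. With mouse as a term the counts were 514 and 48, and 27 genes were then higher and 7 lower in the lung in both subclones. Those included CYP1B1 (4.24 ± 0.68 and 5.71 ± 0.81), TNFRSF1B, a TNF receptor (3.33 ± 0.62 and 2.96 ± 0.61), MUC5AC, a secreted mucin (3.19 ± 0.42 and 2.54 ± 0.42), WWC1 (2.34 ± 0.39 and 1.90 ± 0.39), COL1A2 (-2.58 ± 0.40 and -1.89 ± 0.38) and TNC (-0.86 ± 0.17 and -1.03 ± 0.17). Genes named from the fit with a mouse term were chosen by the same rule after the data had been seen.

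Of 26 genes of the TNF and NF-kB response, 0 passed in either subclone, and 14 and 16 were higher in the lung when adjusted over the list alone. In the fit with a mouse term 5 rose in subclone 2, among them IL6 (main estimate 1.88 ± 0.58) and RELB (1.12 ± 0.30), and RELB alone in subclone 13 (1.04 ± 0.30). The medians were 1.09 and 1.25 (adjusted p = 0.210 and 0.0658 with an estimated correlation). The 13 mitochondrially encoded genes had 0 members past the threshold, 11 in each subclone adjusted over the list alone, and 12 and 10 with mouse as a term. Their medians were 1.17 and 1.34, and the list call held with an estimated correlation in subclone 13 alone (adjusted p = 0.174 and 0.0371 with an estimated correlation) and in neither with mouse as a term (adjusted p = 0.219 and 0.0519 with an estimated correlation). Of 28 interferon response genes 0 passed in subclone 2, where 10 rose with mouse as a term and the median was 0.84 (adjusted p = 0.369 with an estimated correlation). The count in subclone 2 was 94 in 1 of 9 other groupings of the same 6 samples, which points to structure among these samples beyond organ. That grouping kept some samples of the same mouse together; among the groupings that, like the real one, part every pair from the same mouse, the highest count was 0.

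**Figure D4:**
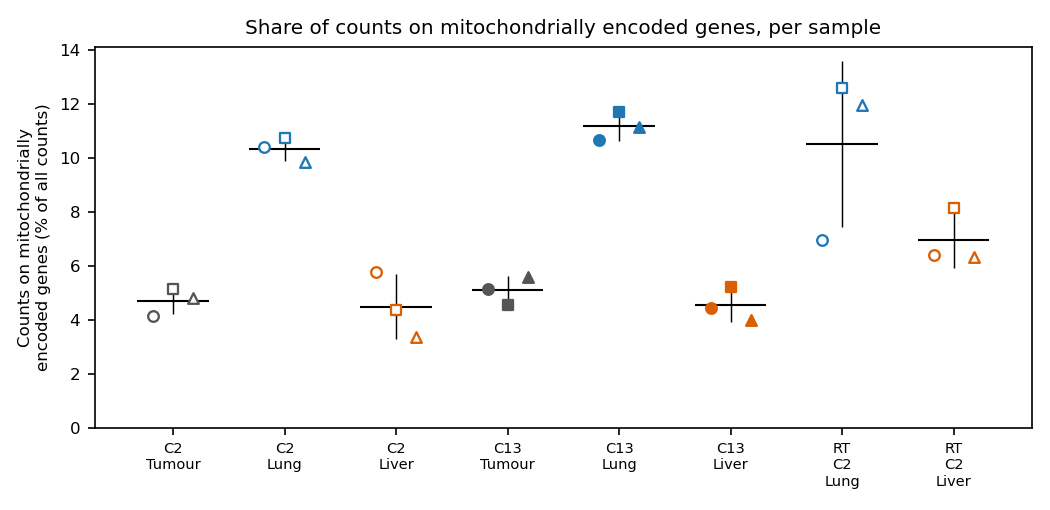
Percent of each sample's counts on mitochondrially encoded genes, by group; symbols are mice 1 or 4 (circle), 2 or 5 (square) and 3 or 6 (triangle), open for subclone 2 and filled for subclone 13, horizontal lines are means and vertical lines are SD (n = 3). The lung means are 10.3% and 11.2% in the first experiment and 10.5% in the retransplantation experiment, and the liver means are 4.49%, 4.56% and 6.97%.

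Subclone 13 differed from subclone 2 in every organ. SPARC, a matrix-associated glycoprotein, was higher in subclone 13 by 4.46 ± 0.43 in tumours (575 ± 127 against 26.1 ± 10.2 CPM), by 4.73 ± 0.44 in lung and by 4.64 ± 0.43 in liver metastases, with edgeR adjusted p of 9.61e-05, 5.13e-05 and 5.84e-05. NGFR, the low-affinity neurotrophin receptor, was higher by 4.78 ± 0.69, 5.40 ± 0.71 and 6.0 ± 0.73. CYGB, cytoglobin, was higher by 3.63 ± 0.60, 3.93 ± 0.61 and 3.10 ± 0.58, PLTP, a phospholipid transfer protein, by 2.04 ± 0.38 in lung and 2.19 ± 0.38 in liver metastases, and CA12, a carbonic anhydrase, by 2.11 ± 0.35, 1.75 ± 0.35 and 2.24 ± 0.35 in tumours, lung and liver. These 5 were the genes called higher in all 3 organs; none was called higher in subclone 2 in all 3. The same counts were 28 and 5 with mouse as a term. Some calls of the 5 genes rested on the settings. With only the groups compared edgeR lost CYGB in tumours and liver (adjusted p = 0.104 and 0.266), PLTP in liver (0.266) and CA12 in lung and liver (0.271 and 0.0849). CA12 in lung was also lost with RLE scaling (0.0656) and with 1 library in place of the 3 summed (0.0525 and 0.0598).

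In the fit without a mouse term, MHC class II genes were called higher in subclone 13 mainly in tumours. There 6 of 9 rose (HLA-DPB1 by 6.42 ± 1.16, HLA-DPA1 by 5.86 ± 0.97, HLA-DRB1 by 5.51 ± 0.88, HLA-DRA by 4.75 ± 0.69, HLA-DMA by 2.93 ± 0.45 and CD74, the invariant chain, by 2.57 ± 0.47), and 9 rose adjusted over the list alone. In lung metastases HLA-DRA alone passed (3.72 ± 0.66; 9 adjusted over the list alone, 7 with mouse as a term), and in liver metastases none did (7 adjusted over the list alone, 6 with mouse as a term). With only the groups compared edgeR lost HLA-DRA in lung (adjusted p = 0.139). The medians were 4.75, 3.49 and 2.67, and with an estimated correlation the list call held in tumours alone (adjusted p = 0.0168, 0.0833 and 0.194 with an estimated correlation) and in none with mouse as a term (adjusted p = 0.0648, 0.210 and 0.283 with an estimated correlation). CIITA, the master regulator of these genes, had an adjusted p of 0.0907 in tumours, and of 0.00555 with mouse as a term. HLA-DRA averaged 287 ± 81.9 CPM in subclone 13 tumours and 10.6 ± 2.91 CPM in subclone 2 tumours. The samples of the subclones were also apart in the metastases. HLA-DRA had 103 CPM and above in subclone 13 lung samples against 28.7 CPM and below in those of subclone 2. In liver samples it had 56.3 CPM and above against 20.4 CPM and below. A list of 8 leukocyte markers, with 0 members past the threshold, was also higher in subclone 13. Its medians were 1.01, 0.87 and 0.56 in tumours, lung and liver (camera adjusted p = 0.00589, 0.0328 and 0.0107; adjusted p = 0.0878, 0.273 and 0.158 with an estimated correlation). PTPRC, 1 leukocyte transcript, averaged 0.107 and 0.509 CPM in tumours of subclones 13 and 2.

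In edgeR without a mouse term fewer genes were called lower than higher in subclone 13. With that term this held in tumours and liver but not in lung (132 higher and 137 lower). The balance depended on mouse 1 and on the tool. Without mouse 1 and without that term edgeR called 35 higher and 45 lower in tumours and 25 and 25 in lung. The 6 compared samples alone gave 8 and 9 in lung, and DESeq2 without that term called 111 and 114 in lung. PRSS2, a trypsinogen, was lower in lung (-4.59 ± 0.71; adjusted p = 0.00833) and liver metastases (-4.32 ± 0.70; adjusted p = 0.0181), as was EPHB6, a kinase-dead Eph receptor (-6.93 ± 1.09 and -4.99 ± 0.95). In tumours both passed only with mouse as a term (PRSS2 -2.87 ± 0.52 and EPHB6 -3.62 ± 0.71). With only the groups compared edgeR lost EPHB6 in lung and liver (adjusted p = 0.0806 and 0.156). MISP, an actin-bundling protein of the mitotic spindle, was lower in the lung (-1.65 ± 0.28). TERT, the catalytic subunit of telomerase, did not pass in the fits without a mouse term; with that term it was lower in all 3 organs (-2.67 ± 0.46, -1.95 ± 0.44 and -2.12 ± 0.45). In all, 19 genes differed in tumours (18 higher in subclone 13), 32 in lung (21 higher) and 43 in liver metastases (35 higher), and 88, 269 and 262 (60, 132 and 170 higher) with mouse as a term. Leaving out samples or mice gave 1 to 80, 1 to 50 and 1 to 95 genes, and fits of the 6 compared samples alone gave 13 in tumours, 17 in lung and 3 in liver metastases.

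**Figure D5:**
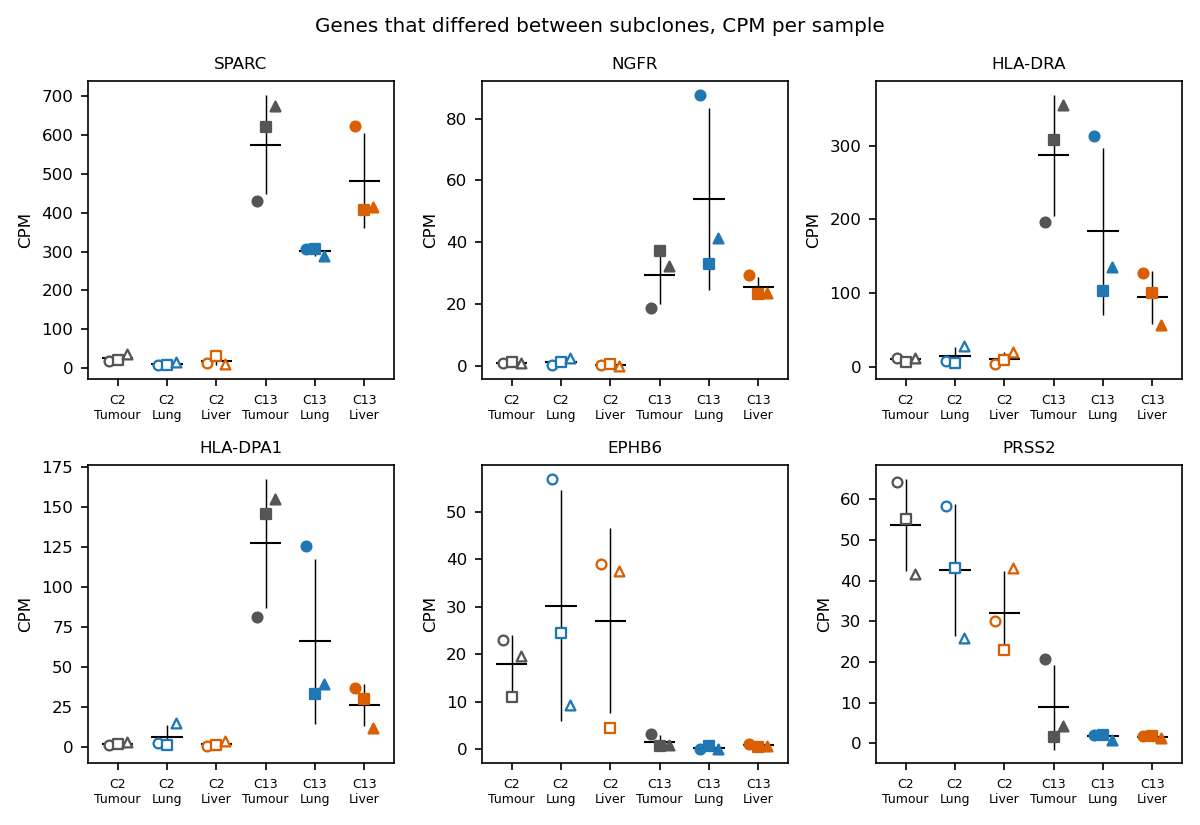
CPM (TMM-scaled) of 6 genes in each sample of the first experiment, by subclone (C2, C13) and organ; symbols are mice 1 (circle), 2 (square) and 3 (triangle), horizontal lines are means and vertical lines are SD (n = 3). SPARC averaged 575 CPM in subclone 13 tumours and 26.1 CPM in subclone 2 tumours.

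Whether organ effects differed between the subclones depended on the tool and its settings. The tests of the difference itself called 0 genes in edgeR for lung against tumour, liver against tumour and lung against liver, with smallest adjusted p of 1.0, 0.331 and 1.0 and with 138, 297 and 345 genes at an unadjusted p under 0.05. DESeq2 called 0, 2 and 0. In fits with mouse as a term edgeR called 0, 1 and 0 and DESeq2 called 1, 24 and 18. Without a filter on low counts edgeR called 6, 35 and 21. The MHC class II list had a median of -1.78 in the difference for liver against tumour (all 9 members negative, 0 past the threshold; adjusted p = 0.985 with an estimated correlation). The immediate early list had medians of -0.32 and -0.65 in the differences for lung and for liver against tumour (19 of 19 and 17 of 19 members negative; adjusted p = 0.914 and 0.985 with an estimated correlation). Across 17418 genes, which are not independent replicates, the fold changes of the 2 subclones had correlations of 0.47, 0.35 and 0.32 in the 3 organ comparisons. In simulated data the edgeR tests recovered 25.8%, 31.8% and 40.9% of genes whose effects differed by 2 on the log2 scale, and 71.2%, 83.3% and 71.2% with mouse as a term. Those data were simulated from the fit with that term, which favours it.

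In the retransplantation experiment edgeR called 0 of 17549 genes between samples labelled lung and liver (smallest adjusted p = 0.0774; 2198 genes at an unadjusted p under 0.05), and DESeq2 called 401 (673 with mouse as a term). With mouse as a term edgeR called 84, 69 higher and 15 lower in the lung; that fit had 2 residual degrees of freedom. Genes higher in the lung with that term included CXCL8 (main estimate 2.23 ± 0.26) and CXCL1 (2.18 ± 0.39), 2 neutrophil chemokines, TNFAIP3, a negative regulator of NF-kB (1.66 ± 0.25), and COL3A1 (4.44 ± 0.42). Genes lower in the lung with that term included HMOX1, heme oxygenase 1 (-2.27 ± 0.43), AKR1C2, an aldo-keto reductase (-2.48 ± 0.52), SERPINA5 (-2.77 ± 0.53) and LCN1 (-3.27 ± 0.94).

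Of 26 genes of the TNF and NF-kB response, 0 passed, 16 rose adjusted over the list alone and 5 rose with mouse as a term; the median was 1.25 (camera adjusted p = 2.43e-15; adjusted p = 0.488 with an estimated correlation). Of 8 MHC class II genes 0 passed, 7 rose adjusted over the list alone and 2 with mouse as a term (HLA-DPB1 3.42 ± 0.63 and HLA-DRA 2.71 ± 0.45), with a median of 2.14 (adjusted p = 0.488 with an estimated correlation). Transcripts of host cells were measured in the same samples: the retransplantation lung samples averaged 4.32 CPM for HBB, 2.35 CPM for SFTPC, 1.75 CPM for PTPRC and 12.9 CPM for COL3A1, and the liver samples averaged 0.181, 0.0110, 0.324 and 0.631 CPM. In the lung samples of subclone 2 in the first experiment the averages were 0.0565, 0, 0.374 and 1.34 CPM. The mitochondrially encoded genes had a median of 0.59 with 0 of 13 members past the threshold (adjusted p = 0.573 with an estimated correlation), and held 10.5 ± 3.09% of counts in lung and 6.97 ± 1.03% in liver samples. The liver sample of mouse 5 lay apart on the first component (score 63.7, others -22.1 to 0.516), and without it 16 genes were called.

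The genes that separated lung from liver in the first experiment were followed in the retransplantation samples. SLC43A2, the 1 gene called higher in the lung, had a log2 fold change of 0.31, and of the 3 genes called lower 1 was lower again (fry p = 0.348, and 0.583 in camera with an estimated correlation). Of the 100 genes with the smallest p among those higher in the lung, 95 were measured and 75 were higher again (median 0.46; fry p = 0.0463, 0.0618 with mouse as a term, and 0.0641 in camera with an estimated correlation). Of the 100 lower in the lung, 99 were measured and 73 were lower again (median -0.20; fry p = 0.449, and 0.491 in camera with an estimated correlation). These p values of limma are model-based and were not adjusted. COL1A2, lower in the lung in the first experiment, was higher in the lung in the retransplantation samples (2.69 ± 0.57; adjusted p = 0.158, and 0.0475 with mouse as a term). It was picked for its change of sign after its values were seen, and its difference between the experiments was -5.30 ± 0.86 (edgeR unadjusted p = 2.91e-05, adjusted p = 0.551). COL1A2 is also on the list of fibroblast, stellate and smooth muscle markers. HBB, SFTPC and PTPRC averaged higher in the retransplantation lung samples than in the liver samples. Whether reads of host cells contributed to the change of sign was not tested.

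The test of the difference between the experiments called 0 of 18950 genes in edgeR (smallest adjusted p = 0.551; 1110 at an unadjusted p under 0.05), and 0 with mouse as a term (smallest adjusted p = 0.0837; 2606 at an unadjusted p under 0.05). DESeq2 called 23, and 574 with mouse as a term. Across 16588 genes measured in both, which are not independent replicates, the lung against liver fold changes had a correlation of 0.13. The 25 genes of mitosis were all lower in this difference (median -0.67, 0 past the threshold; adjusted p = 0.664 with an estimated correlation), and 27 of 28 interferon response genes were higher (median 0.94, 0 past the threshold; adjusted p = 0.711 with an estimated correlation). A change of 2 on the log2 scale in this test was recovered for 6.06% of simulated genes, and for 54.5% with mouse as a term, from whose fit the data were simulated.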

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

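In the difference between the subclones for liver against tumour, ACTG2, a smooth muscle actin, was the 1 gene called with mouse as a term (5.90 ± 0.80; edgeR adjusted p = 0.00861). It was picked out because its organ effect differed between the subclones. Without that term the estimate was 5.73 ± 0.99 with an adjusted p of 0.331. In subclone 13 the liver samples had 20.4, 27.6 and 29.3 CPM and the tumour samples 15.3, 7.68 and 7.84 CPM. In subclone 2 the liver samples had 0.192, 0 and 0.260 CPM and the tumour samples 3.22, 2.23 and 3.32 CPM, so the fold within subclone 2 rests on a few counts. No biological explanation was tested for it.

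All samples of mouse 1 lay apart from those of mice 2 and 3; of the 3 tests, that of depth was written before the data were examined and the others were chosen after the result was seen. A difference between sequencing runs could produce this, but subclone 13 libraries of mouse 1 sequenced in runs 2 and 3 were closer to their own run 1 library than to another mouse in the same run (median ratio of distances 0.444, 0.377 to 0.773 over 6 libraries). After thinning to 11.8 M counts, 6 of 6 samples of mouse 1 still lay beyond all 12 others on the first component, against a cause in depth alone. Mouse 1 had the fewest genes detected in 5 of 6 groups at equal depth, which fewer captured molecules might produce, and this test does not separate that from a difference between animals. These tests concern technical causes; no biological explanation was tested.

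Mitochondrially encoded transcripts were higher in lung than in tumour samples; the test of damaged cells was written before the data were examined and the others were chosen after the result was seen. Reads from mouse lung cells are another technical candidate. The summed host lung list gained 0.0127% of the mitochondrial gain in subclone 2 and -0.0104% in subclone 13. That list already held 28.0 and 38.7 CPM in the tumour samples of subclones 2 and 13, so its sum was not particular to lung samples. Mouse reads were counted only as far as they aligned to human genes, so this test cannot exclude them. Damaged cells that lost cytoplasmic RNA are a technical candidate, because the nuclear transcripts NEAT1 and MALAT1 were also higher (median 1.41; 1.44 ± 0.93 and 1.39 ± 0.78 in subclone 2, 1.1 ± 0.92 and 1.56 ± 0.78 in subclone 13). Their adjusted p were 0.715, 0.640, 0.947 and 0.692, and 0.00604, 0.0106, 0.0367 and 0.00642 with mouse as a term. More mitochondria per cell is the biological candidate, and the nuclear oxidative phosphorylation list had medians of only 0.33 and 0.26, which does not decide it.

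Immediate early genes included 3 and 2 of 19 members called higher in lung than in tumour samples of subclones 2 and 13, while the list calls were lost with an estimated correlation (adjusted p = 0.186 and 0.227 with an estimated correlation); both tests of this pattern were chosen after the result was seen. Dissociation stress, a technical cause, could raise them. Heat shock genes had medians of -0.29 and -0.43, and by the conditions set for it this test could not tell. It concerned only stress with a heat shock response, so stress without that response stays open. A cause shared with the mitochondrial share might also raise them; in liver of subclone 2, where mitochondrial transcripts had a median of 0.35, the immediate early list still had a median of 0.53, and in subclone 13 it had -0.09. A biological response of cells in the lung was not tested.

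The compared samples were regrouped, and this was planned before the data were examined; all groupings of 3 against 3 were used, and 19 others drawn at random for the differences. With 10 groupings of 3 against 3 a share under 0.05 cannot be reached. The real grouping was the only 1 to reach its count (1 of 10) in subclone 2 for lung against tumour (76, highest other 0) and liver against tumour (50, highest other 1), in subclone 13 for the same pairs (73 and 67, highest other 0) and between subclones in tumour, lung and liver (19, 32 and 43, highest other 0). For lung against liver of subclone 2, 2 of 10 groupings reached 4 genes and 1 of them called 94, which points to structure among the samples. The grouping with 94 kept both samples of mouse 1 together, but the other groupings that did so called 0. The source of that structure was not tested. With 0 real calls, all 10 groupings reached the count in subclone 13 and in the retransplantation samples (highest other 0). All 20 groupings used did so for the differences between subclones (highest others 14, 1 and 2997) and between experiments (highest other 0), and the 2997 again points to structure among the samples.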

How the results depend on the processing

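Of 2040 values of named genes from leaving out samples or mice, 1470 kept their status (called or not), 521 lost their call, 49 gained one and 0 reversed. Of 1365 values from other settings 966 kept it, 64 lost their call, 335 gained one and 0 reversed. The size of a change was not weighed. Named genes had all 3 samples of 1 group above all 3 of the other, apart from differences between subclones. Leaving out samples could therefore hardly reverse a direction, and the 0 reversals do not measure robustness. Genes named from the fit with mouse as a term had passed there. That fit is among the other settings, so part of the gains was fixed in advance. Counts of called genes were not robust, and the cause was not tested. With the mouse number as a replicate block, subclone 2 had 532 (lung against tumour), 292 (liver against tumour) and 514 (lung against liver) genes, subclone 13 had 503, 318 and 48, the subclones differed in 88 (tumour), 269 (lung) and 262 (liver), the difference between subclones for liver against tumour had 1 and the retransplantation samples had 84; the other 3 counts of genes stayed at 0. In the same order, without a filter on low counts the counts were 219, 261 and 247, then 260, 298 and 77, then 118, 221 and 253, with 6, 35 and 21 for the differences between subclones, 718 in the retransplantation samples and 2 between experiments. DESeq2 gave 337, 255 and 277, then 307, 237 and 51, then 83, 225 and 267, with 2 for the difference between subclones in liver against tumour, 401 in the retransplantation samples and 23 between experiments, where its fold changes had a median over all genes of 0.156. With the block DESeq2 gave 1260, 720 and 1431, then 935, 661 and 388, then 279, 779 and 803, then 1, 24 and 18 for the differences between subclones, 673 in the retransplantation samples and 574 between experiments; edgeR without a filter gave 882, 618 and 966, then 766, 664 and 303, then 354, 590 and 667, then 18, 121 and 67, then 1523 and 417. Fits of only the groups compared gave 18, 0 and 0 in subclone 2, 103, 30 and 0 in subclone 13, and 13 (tumour), 17 (lung) and 3 (liver) between subclones. With only the run 1 library of mouse 1, subclone 13 differed from subclone 2 in liver in 26 genes.

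Leaving out each sample or mouse gave 2 to 97, 0 to 99 and 0 to 135 genes in subclone 2, 0 to 145, 0 to 121 and 0 to 1 in subclone 13, 1 to 80, 1 to 50 and 1 to 95 between subclones, 0 to 0, 0 to 0 and 0 to 1 for the differences between subclones, 0 to 16 in the retransplantation samples and 0 to 1 between experiments. The highest counts of the first 9 came without mouse 1. With the block, leaving out a mouse gave 107 to 258, 105 to 213 and 27 to 542, then 84 to 349, 99 to 312 and 6 to 20, then 14 to 144, 16 to 155 and 31 to 183, then 0 to 0, 0 to 7 and 0 to 2, 105 to 149 in the retransplantation samples and 0 to 1 between experiments. Of 149 list calls 14 were kept with an estimated correlation, and the block gave 168. With both the block and an estimated correlation 8 were called, 2 for lung against tumour and 6 for liver against tumour of subclone 13, and none in the other 12 comparisons. Of the 3 genes lower in lung than liver of subclone 2, 1 was lower again and 2 went the other way in the retransplantation samples (fry p = 0.348, and 0.583 in camera with an estimated correlation); the direction was reversed with the top 100 genes (p = 0.449) and with lists from the blocked fit (p = 0.725). The top 100 genes higher in lung (fry p = 0.0463) no longer passed 0.05 with the block (fry p = 0.0618) or with an estimated correlation in camera (p = 0.0641). The top 100 of the blocked fit gave a fry p of 0.0747, and all 284 genes called higher in lung in that fit gave 0.0881. In simulated comparisons of 3 against 3 samples, 1.47% to 14.7% of changes of 1 on the log2 scale were recovered without the block and 35.3% to 50.0% with it. The data were simulated from the fit with the block, which favours that fit.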

Other observations

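LOX, a lysyl oxidase that crosslinks collagen, was the 1 member of 26 hypoxia and glycolysis genes that passed in each comparison with the tumour. In edgeR it fell by 1.79 ± 0.27 and 1.79 ± 0.27 in lung and by 1.78 ± 0.27 and 1.64 ± 0.27 in liver metastases of subclones 2 and 13 (adjusted p = 0.00736, 0.00568, 0.00566 and 0.00747). VEGFC, a lymphangiogenic factor, fell by 1.05 ± 0.22 and 1.25 ± 0.22 in lung metastases and by 1.05 ± 0.22 in liver metastases of subclone 13. Of 15 angiogenesis factors, 0 passed in liver metastases of subclone 2 and 5 fell in each subclone adjusted over the list alone; the medians were -0.60 and -0.32, and both list calls held with an estimated correlation (adjusted p = 0.0266 and 0.0402 with an estimated correlation), but with mouse as a term only that of subclone 13 did (adjusted p = 0.0856 and 0.0466 with an estimated correlation). LATS2, a kinase of the Hippo pathway, fell by 0.97 ± 0.20 in lung and 1.08 ± 0.20 in liver metastases of subclone 2. It belongs to a list of 15 YAP targets whose medians in liver were -0.20 and -0.51 (adjusted p = 0.0550 and 0.0402 with an estimated correlation, and 0.0856 and 0.0466 with mouse as a term).

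With mouse as a term, and chosen by the rule after the data had been seen, RGS1, a regulator of G protein signalling, was higher in lung metastases than in tumours of both subclones (4.57 ± 0.87 and 3.76 ± 0.83; adjusted p = 0.00604 and 0.0172). FAP, a membrane protease, was lower (-4.61 ± 1.07 and -5.29 ± 1.12; adjusted p = 0.0224 and 0.0130), and NNMT, a nicotinamide methyltransferase, was lower in liver metastases (-4.10 ± 0.59 and -3.19 ± 0.54). Without that term their adjusted p were 0.146 and 0.184, 0.203 and 0.121, and 0.0513 and 0.129.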
